A study of Homo sapiens with 6 samples.

How the data were processed

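Total RNA from 92.1 uveal melanoma cells was profiled on Illumina HT-12 bead arrays after transfection of a control siRNA or a BAP1 siRNA, with 3 samples per group. Per the labels, each sample was a separate transfection, cells grew in medium with 10% fetal bovine serum, RNA was collected 5 days after transfection, and labelled RNA was made with an Illumina amplification kit. The p-values therefore measure the spread between transfections of a cell line. The groups were taken from the sample titles.

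The deposited non-normalized table holds a probe intensity on a linear scale for each array, not background-subtracted as its values show, and, per the file headers, a detection p-value that a probe's signal comes from the negative controls. A second deposited table holds log2 intensity values, quantile normalized between arrays per the file headers. The series matrix holds the same deposited log2 values, with 0 cells differing, so as an alternative it repeats that table. Their correlation with log2 of the raw intensities was at least 0.9996 on each array, so scale and direction are known and no centring was applied. The submitters' processing notes name limma with no version or role; the scanner software is not given in the sources used here, nor are chips, slides or scan dates, so arrays could not be grouped by chip.

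Starting from the non-normalized table, the background was corrected with limma's normexp method, with the negative controls' mean and spread inferred from the detection p-values and an offset of 16, and arrays were quantile normalized and put on the log2 scale (R 4.3.3, limma 3.58.1, statmod 1.5.0). Background correction widens fold changes of dim probes, and quantile normalization removes any shift shared by all genes. Probes entered with a detection p under 0.05 on at least 3 arrays. Of 47224 probes, 30110 had 1 gene symbol in the platform annotation used here, 8 had several and 17106 had none, and the latter are unnamed here. Symbols were updated through Entrez IDs with a gene table of the GRCh38.p14 assembly, which matched 30071 probes, and 39 kept the annotated symbol. Of 14657 detected probes, 11478 had 1 symbol, and each of the 9141 genes was represented by its detected probe with the highest mean, chosen among several for 1955 genes. No coordinates were used. The BAP1 transcript, planned as a check of the knockdown, had 0 named probes in the tables used and is not analysed here.

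Detected probes per array ranged from 14204 to 15464, and median raw intensities from 143.3 to 162.8. Correlations of log2 signals between arrays ranged from 0.963 to 0.984. For a gene detected on every array of a group but not on every array of the other, the fold printed is a lower bound: the detected group's mean of normalized log2 values against the mean, over the other group's arrays, of the higher of that array's lowest detected signal and the probe's own value. This bound allows for the detection limit alone, not for sampling error or another normalization.

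Knockdown and control were compared with limma (lmFit and eBayes), with group as the only term and Benjamini-Hochberg adjustment over the 9141 genes. Calls were made at an adjusted p under 0.05. An exact permutation test of 3 against 3 samples cannot go below p = 0.1 for a single gene. Of 26 gene lists fixed from general knowledge before the data were examined, 22 had at least 3 tested members and were tested with limma's camera, two-sided, with a preset correlation of 0.01 and adjustment over the 22 lists. With the correlation between genes estimated from the residuals, 0 of 22 lists passed, and 2 had an unadjusted camera p under 0.05. The estimate was 0.0016 for the HOX list, -0.027 for neural crest and -0.025 for axon guidance, all below the preset 0.01. For these lists a higher correlation between members is therefore not why the call was lost. Counts adjusted over a list alone used the same p-values with the adjustment over its members. Named genes were fixed by rule before the data were examined: BAP1, the 12 largest increases and 12 largest decreases among called genes whose groups did not overlap, with unnamed loci replaced by the next gene, every tested member of the tumour classifier lists, and in each other list up to 4 members with the smallest p and up to 2 of the brightest that did not pass. The rule gave 144 genes. All of them entered the comparison of alternatives, but the results describe a selection of the genes that did not pass, made after their values were seen and leaving out most of those whose sign depends on the processing. Each rule gene whose sign changed under an alternative is given with its values under the dependence on the processing. Genes outside the rule are named as such.

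The labels number the replicates 1 to 3 in both groups without saying that a number marks a shared day. Deviations from the group means correlated at 0.560, 0.381 and 0.496 between same-numbered samples of the 2 groups and between -0.427 and -0.039 for different-numbered samples of the 2 groups. Deviations cancel out within a group, so the negative values follow in part from the positive ones and are not separate evidence. Each same-numbered pair was above 0.1, the threshold set for taking the numbers as pairs, so blocked values are given where they change a call described below. The pairing was thus taken from these same data. The block leaves 2 residual degrees of freedom per gene, against 4 with no block. Alternatives were the submitters' table, no background correction, an offset of 50, scaling to the 75th percentile or the median, no detection filter or a strict filter (detection p under 0.01 on all 6 arrays), every detected probe, the mean of a gene's probes, an intensity trend with robust moderation, array weights, the replicate block, each array left out, stricter thresholds, camera with an estimated correlation, and limma's fry.

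The procedure was tested on simulated data built from the real means and spreads of the 9141 genes in the comparison of BAP1 knockdown with control, with 100 genes changed at each size. At a log2 change of 1 it recovered 65% of changed genes, and at 2 it recovered 98%, with 4 false calls, against 0 calls when nothing was changed. With the replicate block the shares were 61% and 84%, with 2 false calls. A simulated list shifted upward was found, and 0 of 19 unshifted lists were called. Simulated genes varied independently of each other and the lists were random, so list calls were not tested under correlation between members. The simulation with no block held no shared variation of same-numbered samples, so the main fit was not tested under the pairing seen in the data.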

Results

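Gene expression was measured on Illumina HT-12 bead arrays in 92.1 cells, a cell line established from a human uveal melanoma, the pigment cell tumour of the eye. Cells received either a control siRNA or an siRNA against BAP1, a nuclear deubiquitinating enzyme that is often lost in uveal melanomas that spread, and RNA was taken 5 days later. Each group held 3 separate transfections, so 6 arrays were compared. Each array detected between 30.1% and 32.7% of its 47224 probes, and 9141 genes had a named probe detected on at least 3 arrays. The number of arrays limits the precision of every value below. The comparison asked which transcripts differ when BAP1 is depleted in a uveal melanoma line. The BAP1 transcript itself was not analysed here, so the depth of the knockdown in each sample is not given.

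After BAP1 knockdown, 36 genes fell and 2 rose at an adjusted p under 0.05 in limma's moderated test. The largest fall of a named gene was in RNU4-2, a spliceosomal small nuclear RNA, from a log2 intensity of 9.34 ± 0.86 in control cells to 6.10 ± 0.46 after knockdown (SD, n = 3 each; adjusted p = 0.0223). It was detected on 1 of the 3 knockdown arrays, so the estimated fall is at least 8.09-fold in these values. In the submitters' values, without background correction, its log2 change was -2.09 ± 0.30 (SE). RN7SK, the small nuclear RNA that holds back transcription elongation, fell from 10.96 ± 0.41 to 9.15 ± 0.37 (adjusted p = 0.0282), and SCARNA13, a guide RNA of Cajal bodies, from 8.05 ± 0.24 to 6.33 ± 0.09 (adjusted p = 0.0127). Among protein-coding genes, the cytoskeletal adaptor PDLIM3 fell 3.72-fold and IGFBP4, a secreted binding protein for insulin-like growth factors, fell 3.54-fold. CYFIP2, a member of the actin-regulating WAVE complex, was also detected on 1 knockdown array and fell at least 2.96-fold. Both genes that rose did so in all 3 knockdown samples, each of which lay above all 3 controls. PPP3CB, a catalytic subunit of the phosphatase calcineurin, rose from 8.29 ± 0.09 to 9.43 ± 0.07 (adjusted p = 0.0187) and the long non-coding RNA SLC9A3-OT1 rose from 8.83 ± 0.23 to 9.99 ± 0.03 (adjusted p = 0.0269).

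The remaining large decreases lay between 2.80-fold and 2.98-fold for BRI3, the fibroblast growth factor receptor FGFR3, the secreted serine protease HTRA1 and the calcium-binding protein S100A1. Their log2 changes were -1.57 ± 0.15 (SE) for BRI3, -1.56 ± 0.24 for FGFR3, -1.55 ± 0.24 for HTRA1 and -1.49 ± 0.22 for S100A1, with adjusted p from 0.0127 to 0.0404. SH3GL3, an endophilin of membrane traffic, and LYPD6B were detected on all 3 control arrays and on 0 knockdown arrays. SH3GL3 was therefore at least 1.85-fold lower (adjusted p = 0.0135) and LYPD6B at least 1.66-fold lower (adjusted p = 0.0135). RNU4-2, RN7SK and other small nuclear RNA genes have near-identical copies in the genome that a probe could also bind, so these values are uncertain as to the copy. Of the 38 genes, 5 had other detected probes, and 5 of those 6 probes moved the same way. The exception was RIOK1, an atypical kinase outside the naming rule and picked out after its values were seen, whose brighter probe fell by 1.13 (log2) while the other stood at 0.04 ± 0.22 (SE).

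**Figure D1:**
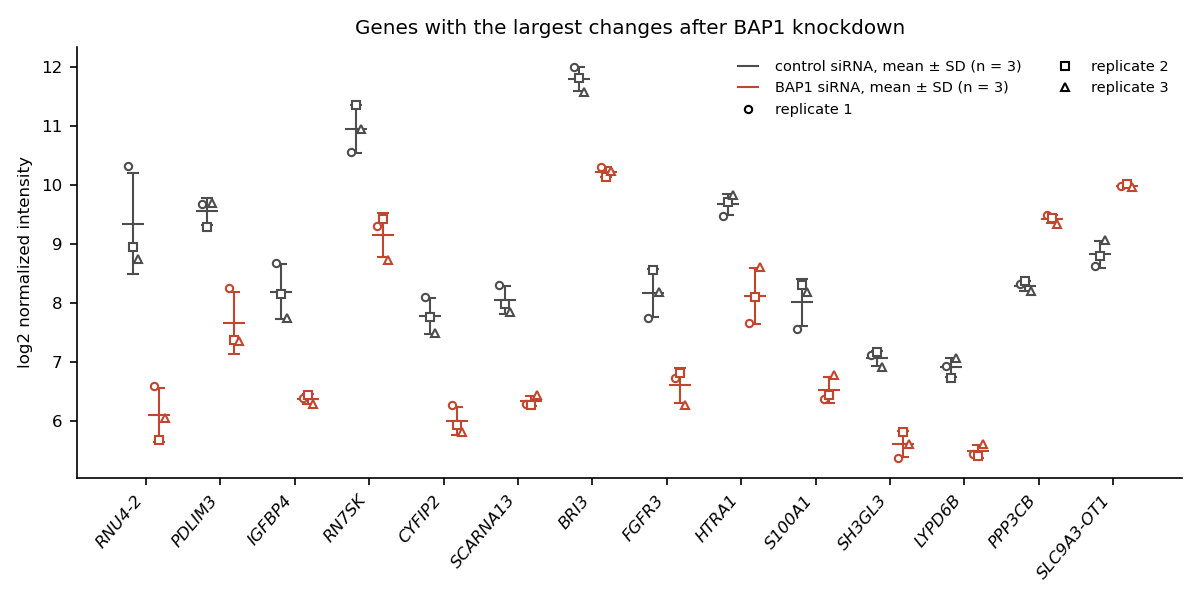
Log2 normalized intensity (vertical axis) of the 12 named genes with the largest estimated falls and the 2 genes that rose, in control cells (grey) and after BAP1 knockdown (red). SH3GL3 and LYPD6B, detected on 0 knockdown arrays, are ranked by their estimates. Their lower bounds lie under the fall of RPL28, which is not shown. Open symbols are single arrays, horizontal ticks with bars are the mean ± SD of 3 arrays, and in each gene the 3 knockdown arrays lie apart from the 3 control arrays, with RNU4-2 falling from 9.34 to 6.10.

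Same-numbered transfections varied together, and with the replicate number as a block 42 genes rose and 236 fell, among them all 38 of the genes above. With no block, 1033 of the 9141 genes had an unadjusted limma p under 0.05, and the groups did not overlap in 17.0% of genes. For independent samples chance gives 457 genes and 10%, but same-numbered samples varied together. Other splits of the 6 samples gave 103 to 932 genes, and 103 to 127 where they parted every pair. The value of 457 is therefore no firm baseline. The counts rest on all 6 arrays: higher and lower genes numbered 2 and 19 without control replicate 1, 1 and 14 without control replicate 3, and 0 and 1 without BAP1 knockdown replicate 1. They were 0 and 0 without control replicate 2, without BAP1 knockdown replicate 2 and without BAP1 knockdown replicate 3, where 813, 793 and 813 genes still had an unadjusted limma p under 0.05.

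Of 39 listed HOX genes, which set positional identity in the embryo, 12 were tested, 17 were not detected and 10 had no named probe. HOXA genes were not among those tested. Of the 12 tested genes, HOXC8 fell from 9.65 ± 0.01 to 8.36 ± 0.11 (adjusted p = 0.0135) and 11 did not pass. HOXC9 was detected on 3 control and 0 knockdown arrays, at least 1.30-fold lower (adjusted p = 0.214, and 0.0335 with the replicate block). HOXD1 differed by -1.05 ± 0.35 (SE; adjusted p = 0.311, and 0.0380 with the block), and HOXB7 by -0.40 ± 0.15 (adjusted p = 0.345). Adjusted over the list alone, 2 HOX genes were lower, and in the blocked fit adjusted the same way 5 were lower and 1 higher. As a set the tested HOX genes were lower than other genes (camera adjusted p = 0.00837, but 0.353 with an estimated correlation). Their median log2 change was -0.26, or -0.24 with partly detected genes at their bounds. Of 11 tested axon guidance and neuronal genes, EFNB2, a membrane-bound ephrin ligand, fell by at least 1.41-fold (adjusted p = 0.0282), while SEMA4D at -0.58 ± 0.16 (adjusted p = 0.192) and CNTN1, detected on 1 knockdown array and at least 1.15-fold lower (adjusted p = 0.383), did not pass. This set was also lower (camera adjusted p = 0.0359, but 0.353 with an estimated correlation), with a median of -0.52, or -0.31 with EFNB2 and CNTN1 at their bounds. Adjusted over the list alone, 2 genes were lower, and 6 in the blocked fit adjusted the same way. The axon guidance call was also lost without control replicate 2 (adjusted p = 0.158), without BAP1 knockdown replicate 1 (0.0737), without BAP1 knockdown replicate 2 (0.0645), with the strict detection filter (0.285) and with no detection filter (0.236).

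In the neural crest list, the embryonic lineage from which pigment cells arise, 0 of 9 tested genes passed, and 1 was lower adjusted over the list alone. ERBB3, a neuregulin receptor, differed by -1.26 ± 0.26 (SE; adjusted p = 0.0935, and 0.0150 with the replicate block), and SNAI2 by -0.41 ± 0.14 (adjusted p = 0.314). The set was lower (camera adjusted p = 0.0298, median -0.21), and this was lost with an estimated correlation (adjusted p = 0.353), without control replicate 1 (adjusted p = 0.0896), without BAP1 knockdown replicate 1 (adjusted p = 0.0662), with the mean of each gene's probes (adjusted p = 0.0884) and with no detection filter (adjusted p = 0.317). Pigment cell identity genes showed no shift past the threshold as a set: 0 of 26 tested members passed, as over the list alone. The median change was -0.09 (camera adjusted p = 0.540). The mean change was 0.014 without control replicate 1 and -0.19 without control replicate 3. PMEL, the scaffold protein of melanosomes, stood at 14.83 ± 0.22 in control cells and 14.58 ± 0.14 after knockdown (adjusted p = 0.658), and the melanosome transport gene RAB38 at 13.51 ± 0.17 and 13.37 ± 0.15 (adjusted p = 0.810). LEF1, a Wnt pathway transcription factor, differed by -0.75 ± 0.18 (SE; adjusted p = 0.149) and QPCT by -0.83 ± 0.31 (adjusted p = 0.357). With the block these 2 genes passed (adjusted p = 0.0283 for LEF1 and 0.0426 for QPCT), and in the blocked fit adjusted over the list alone 3 genes were lower and 1 higher.

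Genes of a published tumour classifier separate uveal melanomas of low (class 1) from those of high (class 2) metastatic risk, and they were chosen on tumours other than these samples. Of the 7 tested genes that are high in class 1 tumours, 0 passed, also adjusted over the list alone, and 6 of the 7 estimates lay above 0. The log2 changes were 0.28 ± 0.16 (SE) for FXR1, 0.24 ± 0.19 for EIF1B, 0.17 ± 0.15 for LTA4H and 0.10 ± 0.17 for MTUS1, against -0.24 ± 0.18 for ID2, with adjusted p from 0.582 to 0.897. LMCD1 was detected on 2 control arrays and 1 knockdown array and is given no fold (adjusted p = 0.965). SATB1 was detected on 0 control arrays and 3 knockdown arrays, at least 1.18-fold higher (adjusted p = 0.369). Tested as a set, they gave a camera adjusted p of 0.189, with a median of 0.17. Of the genes high in class 2 tumours, 2 were tested and 0 passed. RAB31, a small GTPase, differed by -0.78 ± 0.14 (adjusted p = 0.0691), opposite to its direction in class 2 tumours. It passed adjusted over the list alone and with the replicate block (adjusted p = 0.0272). HTR2B, a serotonin receptor, spread widely within both groups, at 9.34 ± 0.82 and 9.39 ± 0.84 (SD, n = 3 each; adjusted p = 0.985). The estimates for LMCD1 and HTR2B changed sign when single arrays were left out, ranging from -0.34 to 0.33 and from -0.41 to 0.43.

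Of 18 tested mesenchymal and matrix genes 0 passed and 2 were lower adjusted over the list alone. With the replicate block 3 were lower adjusted over the list alone, and 3 fell over all genes. COL4A2, a basement membrane collagen, was detected on 3 control and 0 knockdown arrays, at least 1.70-fold lower (adjusted p = 0.0765, and 0.0218 with the block). The integrin subunit ITGAV differed by -0.87 ± 0.17 (SE; adjusted p = 0.0894, and 0.0143 with the block). The third was SPARC, a matrix glycoprotein outside the naming rule and picked out after its values were seen, at -0.65 ± 0.36 (adjusted p = 0.581, and 0.0400 with the block). VIM, encoding vimentin, stood at 13.31 ± 0.41 and 13.73 ± 0.32 (SD; adjusted p = 0.606). The set did not pass (camera adjusted p = 0.280). Of the epithelial junction and keratin list only 4 of 26 genes were tested and 0 passed, also adjusted over the list alone. ESRP1, an epithelial splicing regulator, was at 0.39 ± 0.15 (adjusted p = 0.400) and the desmosomal gene DSP, detected on 1 knockdown array, at least 1.09-fold lower (adjusted p = 0.720), and the set gave a camera adjusted p of 0.940. Markers of other cell types were sparse: 2 of 12 fibroblast genes and 2 of 15 leukocyte genes were tested, and 0 of them passed. FBLN1, on the fibroblast list, was at -0.51 ± 0.15 (adjusted p = 0.25) and was lower adjusted over the list alone. CD68, on the leukocyte list, was at -0.37 ± 0.29 (adjusted p = 0.727), and 0 leukocyte genes passed over that list alone.

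Several antigen presentation and interferon-stimulated genes had lower estimates without passing the test over all genes. Of 14 tested antigen presentation genes, 4 were lower adjusted over the list alone and 3 fell with the replicate block. These 3 were HLA-DMB, detected on 2 knockdown arrays and at least 2.45-fold lower (adjusted p = 0.126, and 0.0250 with the block), the peptide transporter TAP1 at -0.94 ± 0.29 (SE; adjusted p = 0.254, and 0.0120 with the block) and the class I gene HLA-B at -0.75 ± 0.15 (0.0935, and 0.0308 with the block). HLA-F was at -0.73 ± 0.18 (adjusted p = 0.173). Of the 14 genes 9 lay below 0 and 5 above, with a median of -0.10. The set gave a camera adjusted p of 0.0622. Over the alternatives it ranged from 0.0141 with no background correction to 0.579 with the block and an estimated correlation. Of 22 tested interferon-stimulated genes, 2 were lower adjusted over the list alone and 3 fell with the block. They were UBE2L6 at -0.998 ± 0.24 (adjusted p = 0.164, and 0.00934 with the block), ISG20 at -0.79 ± 0.14 (0.0632, and 0.0250 with the block) and IFI6 at -0.61 ± 0.18 (0.246, and 0.0463 with the block). In the blocked fit adjusted over the list alone, 5 were lower. Of the 22 genes 15 lay below 0 and 7 above, with a median of -0.09, or -0.08 with partly detected genes at their bounds. As a set the interferon-stimulated genes gave a camera adjusted p of 0.0843. It ranged over the alternatives from 0.0387 with the strict detection filter to 0.708 with an estimated correlation.

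Cell-cycle genes had small, widely shared lower estimates. Of 44 tested mitosis and G2/M genes, 38 lay below 0 with a median of -0.24, and of 38 tested DNA replication and G1/S genes, 33 lay below 0 with a median of -0.25. In both lists 0 genes passed, with the block and adjusted over the list alone too. The proliferation-associated transcription factor FOXM1 was at -0.52 ± 0.21 (SE; adjusted p = 0.408), the survivin gene BIRC5 at -0.47 ± 0.17 (0.358), the mitotic kinase CDK1 at -0.32 ± 0.15 (0.476), the clamp loader RFC4 at -0.45 ± 0.21 (0.490) and the replicative helicase subunit MCM7 at -0.26 ± 0.20 (0.716). As sets both were lower (camera adjusted p = 0.00401 for mitosis and 0.00837 for replication), but with an estimated correlation the camera adjusted p was 0.741 and 0.786. The estimated correlation between members was 0.52 for mitosis and 0.69 for replication, far above the preset 0.01. The preset correlation thus makes these p-values too small, and members below 0 do not count as separate evidence. The mitosis call was lost without control replicate 3 (adjusted p = 0.394) and without BAP1 knockdown replicate 1 (0.522). The replication call was lost without control replicate 1 (0.594), without control replicate 2 (0.229) and without BAP1 knockdown replicate 3 (0.209).

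In the lists of p53 targets and heat shock chaperones 0 genes passed, also adjusted over the list alone. In the blocked fit adjusted the same way, 3 p53 targets were higher and 1 lower, and 2 chaperones were higher. Of 19 tested p53 targets, 13 lay above 0. SESN2, a stress-induced regulator of growth signalling, was at 0.71 ± 0.21 (SE; adjusted p = 0.240, and 0.0487 with the replicate block), and the pro-apoptotic gene BAX at 0.46 ± 0.18 (adjusted p = 0.396). The set gave a camera adjusted p of 0.110 and passed with the block (0.0471), with the strict detection filter (0.0387), without control replicate 1 (0.0313) and without BAP1 knockdown replicate 3 (0.0207). It reached 0.708 with an estimated correlation, and 0.579 with the block as well. Of 18 tested chaperones, 13 lay above 0. The co-chaperone DNAJA1 was at 0.37 ± 0.16 (adjusted p = 0.428) and HSPA1B, a stress-inducible chaperone, at 0.66 ± 0.48 (adjusted p = 0.703, and 0.0497 with the block). The chaperone set gave a camera adjusted p of 0.172 and passed with the block (0.0400), with array weights (0.0439), without control replicate 1 (0.00161) and without BAP1 knockdown replicate 3 (0.0138). It reached 0.904 without BAP1 knockdown replicate 1, and 0.579 with the block and an estimated correlation.

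Genes of the BAP1 partner proteins and of the Polycomb complexes, which modify histones, showed no shift past the threshold as sets. Of the tested genes, 9 of 13 partners and 15 of 20 Polycomb genes lay below 0. Of 13 tested partner genes 0 passed, and MBD6 was lower adjusted over the list alone, at -0.70 ± 0.13 (SE; adjusted p = 0.0689, and 0.0267 with the replicate block). The transcription factor FOXK1 was at 0.32 ± 0.14 (adjusted p = 0.466). Of 20 tested Polycomb genes 0 passed, also over the list alone, with JARID2 at 0.48 ± 0.18 (adjusted p = 0.364), KDM2B at -0.32 ± 0.15 (0.465) and RING1 at 12.01 ± 0.09 in control cells and 11.81 ± 0.04 after knockdown (SD; adjusted p = 0.658). The camera adjusted p was 0.291 for the partners and 0.419 for Polycomb.

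Of 15 tested MAPK output genes 0 passed, also over the list alone. In the blocked fit adjusted over the list alone, 1 was lower. ETV4 was at -0.73 ± 0.22 (SE; adjusted p = 0.253, and 0.0409 with the replicate block) and the cyclin gene CCND1 at -0.41 ± 0.14 (0.312). CXCL8, detected on 1 control array and 3 knockdown arrays, was higher in 3 of 3 pairs (0.301). Of the 15 genes 9 lay below 0 and 6 above. The camera adjusted p was 0.189 for the set, which passed without control replicate 2 (0.0403) and reached 0.786 with an estimated correlation. Of 14 tested YAP and TEAD targets 0 passed. FOXF2 was at -0.82 ± 0.16 (0.0772, and 0.0287 with the block), lower adjusted over the list alone, and the kinase gene LATS2 at 0.50 ± 0.16 (0.298). In the blocked fit adjusted over the list alone, 2 targets were higher and 1 lower. That set had a median of 0.06, or 0.04 with partly detected genes at their bounds, and a mean of -0.01, and camera placed it up with an adjusted p of 0.721.

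Of 68 tested cytosolic ribosomal protein genes, RPL28 fell 2.68-fold (adjusted p = 0.0269) and 67 did not pass. RPS7 was at 0.75 ± 0.16 (SE; adjusted p = 0.109) and RPL23A at -0.69 ± 0.20 (0.235, and 0.0383 with the replicate block), and ribosomal protein probes can also bind pseudogene transcripts. Adjusted over the list alone, 1 was higher and 1 lower, and in the blocked fit 1 was higher and 2 lower. The list's median was 0.01 and its mean -0.02, with camera down at an adjusted p of 0.940. Of 65 tested oxidative phosphorylation genes 0 passed and 1 was lower over the list alone. NDUFB5, a subunit of respiratory complex I, was at -0.72 ± 0.14 (0.0765, and 0.0285 with the block) and COX4I1 at -0.48 ± 0.15 (0.252). By contrast, NDUFV3 was at 0.64 ± 0.17 (0.194) and UQCR10 at 0.49 ± 0.16 (0.298). Of the 65 genes 45 lay above 0, with a median of 0.03, and camera placed the set up with an adjusted p of 0.572. Of 29 tested hypoxia and glycolysis genes 0 passed and 1 was higher over the list alone, and in the blocked fit 2 were higher and 1 lower. The glucose transporter gene SLC2A3 was at 1.05 ± 0.20 (0.0822, and 0.0271 with the block), ALDOC at -0.55 ± 0.17 (0.253) and GAPDH at 0.13 ± 0.13 (0.803), with a camera adjusted p of 0.589. Of 32 tested amino acid and ER stress genes and 17 tested cholesterol synthesis genes 0 passed, also over each list alone. In the blocked fit over each list alone, 1 stress gene was higher and 1 lower, and 0 cholesterol genes passed. PDIA6, a protein disulfide isomerase, was at -0.78 ± 0.19 (0.163, and 0.0273 with the block), the stress regulator ATF4 at -0.13 ± 0.16 (0.839) and CHAC1 at 0.68 ± 0.20 (0.235). TM7SF2, detected on 2 knockdown arrays, was at least 1.64-fold lower (0.238), SQLE was at -0.30 ± 0.21 (0.697) and INSIG1 at 0.38 ± 0.19 (0.502). Above 0 lay 17 of the 32 stress genes and 9 of the 17 cholesterol genes. The camera adjusted p was 0.540 for the stress list, which passed without control replicate 3 (up, 0.0112) and reached 0.971 without BAP1 knockdown replicate 3. It was 0.799 for cholesterol synthesis, whose median of 0.04 and mean of -0.01 differed in sign.

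**Figure D2:**
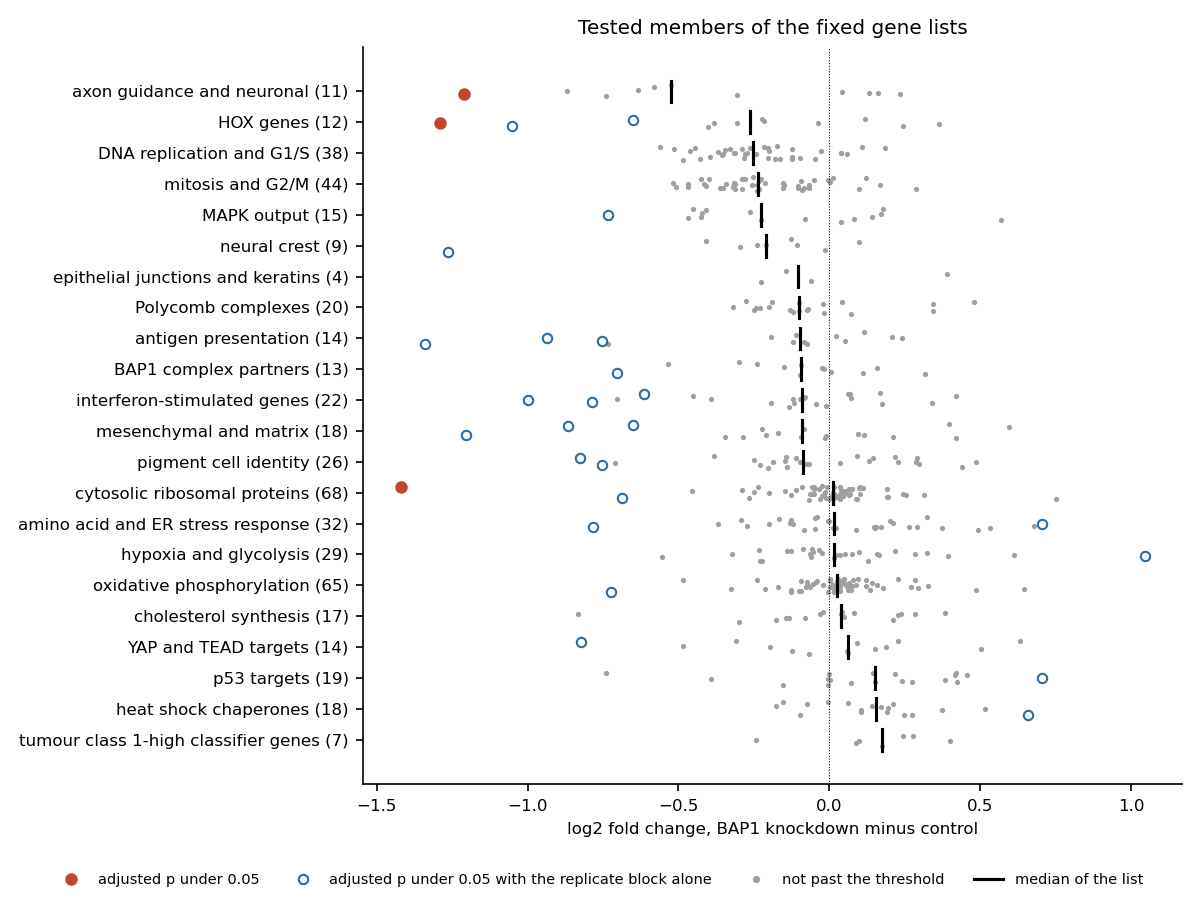
Log2 fold change (horizontal axis, knockdown minus control) of every tested member of the 22 gene lists with a set test, with the number of tested members in parentheses. Red points passed at an adjusted p under 0.05, open blue points passed with the replicate block alone, grey points did not pass, and black bars are list medians, the lowest being -0.52 for axon guidance and neuronal genes, or -0.31 with partly detected genes at their bounds.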

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

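The replicate block combined with the submitters' table, with another detection filter or with an estimated correlation was chosen after seeing the data; the other settings were fixed before. Counts of higher and lower genes, 2 and 36 as reported, were 6 and 62 with the submitters' table (6 and 62 in the series matrix, which holds the same values), 6 and 63 with no background correction, 3 and 61 with an offset of 50, 8 and 81 with an intensity trend and robust moderation, 6 and 57 with array weights, 4 and 43 with the mean of probes, and 1 and 15 with no detection filter, where 20044 genes shared the adjustment. At an adjusted p under 0.01 both were 0. With the replicate block they were 42 and 236, with the block and the submitters' values together 260 and 511, with block and strict detection filter 155 and 301, and with block and no detection filter 0 and 0, although 2705 genes then had an unadjusted limma p under 0.05. Leaving out single arrays gave 0 to 2 higher and 0 to 19 lower genes, with fewer samples in each fit. Percentile scaling, median scaling, the strict filter, all probes and a log2 change of at least 1 kept both counts within 1.5 times. Of the 38 genes, 35 to 38 were called again under each of the other normalizations, 16 with no detection filter and 38 with the block, and 0 changed sign under any setting. Lists past the threshold numbered 5 as reported, 3 with no detection filter, 8 with array weights, 0 with an estimated correlation, 0 with fry (10 when either direction counts), 7 with the block and 0 with the block and an estimated correlation, and 2 to 7 with single arrays left out. The HOX list passed with each array left out. Of the 144 genes of the naming rule, the block raised 23 past the threshold and lowered 0 below it, and it changed no other call among them. The sign of 26 of these 144 genes changed under some setting, 7 with all arrays kept and 19 only with an array left out. Of these 26 genes 0 were called, and their absolute log2 changes were at most 0.22. With the mean of probes TFAP2A went to 0.18 and ZMAT3 to -0.10. With array weights B2M went to -0.0291, ASAP1 to 0.062 and TUBB3 to -0.011. With 75th percentile scaling COX7C went to -0.015 and HSPB1 to 0.018, and HSPB1 to 0.033 with median scaling. With single arrays left out, the log2 changes ranged for ASAP1 from -0.25 to 0.16, ASNS from -0.12 to 0.11, ATP5F1B from -0.017 to 0.11, B2M from -0.049 to 0.11, CCNG1 from -0.045 to 0.18, CD14 from -0.088 to 0.26, COX7C from -0.043 to 0.081, ENO1 from -0.066 to 0.12. They ranged for ETV5 from -0.0805 to 0.19, HSPA8 from -0.23 to 0.032, HSPB1 from -0.12 to 0.17, HTR2B from -0.41 to 0.43, IFITM2 from -0.23 to 0.0398, IFITM3 from -0.21 to 0.17, JUP from -0.38 to 0.12, LMCD1 from -0.34 to 0.33. They also ranged for LUM from -0.35 to 0.25, MYC from -0.24 to 0.00047, PTTG1 from -0.21 to 0.15, RPL41 from -0.0093 to 0.029, RPS12 from -0.013 to 0.025, SEMA6A from -0.0301 to 0.31, SUZ12 from -0.11 to 0.068, TUBB3 from -0.20 to 0.52. Except for smaller sample numbers and the larger number of genes tested, the cause of these differences was not tested. Signal over background limits the genes with undetected arrays, whose folds are given as bounds, or not at all for LMCD1. Chip as a block was not run, since no chips are named, and BAP1 gave no value under any setting.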

Other observations

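Tests of short RNA recovery, promoter class, array scaling and calls among genes detected on every array were chosen after the results were seen. So were those of off-target action, culture growth and the splits of samples for counts of genes. Predictions on background signal, control signal, the Notch pathway and the splits for gene lists were written before those tests were run. Apart from the splits, they concern patterns already seen in the results, and the Notch genes were not among the fixed lists. Calcineurin subunit genes, picked out after their values were seen, moved in opposite directions: PPP3CB rose by 1.13 ± 0.13 (log2, SE) while PPP3CC, another catalytic subunit, fell from 8.34 ± 0.25 to 7.02 ± 0.22 (SD, n = 3 each; limma adjusted p = 0.0280). The groups did not overlap for either gene, so a change in 3 of 3 pairs follows from that and adds nothing. Further small RNAs, also picked out after their values were seen, did not pass with no block and fell in the fit with the replicate block. These were the U3 genes SNORD3A, SNORD3C and SNORD3D (-0.77, at least 1.9-fold lower with 1 knockdown array detected, and -1.20), SNORD13 (-0.87), RNU6-1 (-0.86), SNORA12 (-1.47) and SNORD95 (-0.82), with blocked adjusted p from 0.00963 to 0.0487, while RNY3, detected on 0 control arrays, rose at least 1.48-fold (blocked adjusted p = 0.0236).

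RNU4-2, RN7SK and SCARNA13 were among the genes with the largest falls. A lower yield shared by all short RNAs would have lowered the 72 detected short RNA genes by about as much. Their median change was -0.022 with a median absolute deviation of 0.34, far above the smallest of the 3 falls, -1.71. This argues against a loss shared by all short RNAs, not against one limited to some of them. Had signal near background caused the falls, they were predicted to end in the submitters' values, which have no background correction. All 3 genes kept a limma adjusted p under 0.05 there, though RNU4-2 shrank to -2.09, RN7SK to -1.57 and SCARNA13 to -0.96. These calls therefore do not need background subtraction. Of all 38 called genes 36 were kept in those values, so keeping a call decides little about signal near background. A hypothesis is that genes with their own small nuclear RNA type of promoter may respond to BAP1 loss: the 16 such genes had a median of -0.71 against -0.00 for 56 intron-hosted genes (permutation p = 8e-05, 0.00034 without the called genes and 0.00016 with near-identical copies averaged). The hypothesis leaves out the intron-hosted SCARNA13, which fell (limma adjusted p = 0.0127). It also leaves out the intron-hosted SNORA12 and SNORD95, which fell in the blocked fit, and RNY3, which rose in it. Of the 16 own-promoter genes 13 lay below 0, with RNY1 at -0.06 ± 0.28 (SE). RNY4 at 0.13 ± 0.25 and RPPH1 at 0.43 ± 0.28 lay above 0. Genes in a class are not independent replicates. The classes were compared after the falls were seen, and genes that fell in the blocked fit stay in without the called ones. The permutation p-values therefore do not test the hypothesis. A lower yield limited to the own-promoter genes would give the same difference and cannot be told apart, since the 56 intron-hosted genes make up most of the 72.

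Lower genes made up 94.7% of the calls, while genes whose groups did not overlap split evenly, 774 higher and 777 lower. Dim probes are argued against as the whole cause: among genes detected on every array by the strict filter, 30 of the calls were lower and 2 higher (93.8% lower). The called lower genes' median control signal was 8.77 against 8.19 for all genes. That of 81 uncalled genes with a fall as large as the smallest called one was 7.98, so control signal decides nothing. With the replicate block that filter left 301 lower and 155 higher genes (66.0% lower), against 236 and 42 without it. Both directions gained calls, the higher ones more, so with the block dim probes stay open as part of the imbalance. Array scaling stays open: with quantile, 75th percentile and median scaling lower genes were 92.5% to 94.9% of calls, and 80.4% to 84.9% with the block (65.5% to 70.8% where the background handling differed), but these scalings differ little, moving the median gene by at most 0.019 (log2) against a median SE of 0.18. An siRNA acting on other transcripts cannot be told apart from an effect of BAP1 loss, which is untested beyond the comparison itself, with 0 siRNA sequences in the labels and 1 BAP1 siRNA reagent.

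For the cell-cycle lists, the mean differences over the 3 pairs were -0.31, -0.17 and -0.15 (log2) for mitosis and -0.50, -0.29 and 0.096 for replication, the latter higher in the third pair. Over the 82 genes of both lists they were -0.40, -0.22 and -0.03. Growth differences between cultures cannot be told apart from a response to BAP1 loss, since the cultures are the samples and 3 pairs cannot give an exact two-sided sign-flip p below 0.25, the value found, so that test decides nothing.

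HEY1, a Notch target picked out after its values were seen, was detected on 3 control and 0 knockdown arrays, at least 1.56-fold lower (limma adjusted p = 0.0135). A hypothesis is that lower expression across the Notch pathway may accompany it: 10 of 12 other detected pathway genes lay below 0, with a median of -0.26. Among these 10 were NOTCH1 at -0.04 ± 0.25 (SE), RFNG at -0.05 ± 0.27 and NUMB at -0.01 ± 0.15. Whether a member promotes or restrains signalling was not weighed, so the count concerns expression, not pathway activity. Limma's camera gave a p of 0.0237 with the preset correlation and 0.239 with an estimated one, so the test rests on the preset one. DTX3 was at -0.71 ± 0.21 (SE; adjusted p = 0.243) and DLL3 at -0.61 ± 0.18 (0.243, and 0.0460 with the replicate block), while RBPJ, the pathway's DNA-binding factor, was at 0.53 ± 0.21 (0.390).

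The 6 samples split into 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 2 higher and 36 lower genes, and the highest other split gave 0 in either direction by limma, with 103 to 932 genes at an unadjusted p under 0.05, so 1 of 10 splits reached each count. For gene lists the real split gave 5 and the highest other split gave 6, with 4 of 10 splits reaching 5 or more. The numbers pair the samples, and 4 splits part all pairs: with the replicate block the real split called 278 genes and 7 lists, and the highest of the other 3 called 0 genes and 4 lists. The other 6 splits keep a pair together in a group.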
